A study of Mus musculus with 32 samples.

How the data were processed

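Bulk RNA-seq libraries of flow-sorted adipose tissue macrophages were used, 32 in all, in 8 groups of 4 defined by genotype (A20 knockout in myeloid cells or wild type), diet (HFD or SD for 12 weeks) and population (CD11c+ or CD206+). Groups and replicate numbers were taken from the sample titles. Per the submitters' processing notes, reads were handled with FastQC 0.11.4, Trimmomatic 0.35, TopHat2 2.1.0 and SAMtools 0.1.18 on the mouse build mm10 (GRCm38). The notes give names and versions without roles. By their usual use these are quality control, trimming, alignment and file handling. The read counter, the annotation release, the strand setting, the library kit and the treatment of reads that fit several genes are not given in the sources used here.

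The authors deposited 1 table of whole-number read counts per gene for each library, not normalized, with 24421 genes named by symbol in the same order in each table. A further 5 entries name no gene: they hold reads outside genes, reads that fit more than 1 gene and other unassigned reads. They were kept out of library sizes and tests. Reads outside genes came to 5.16% to 11.1% of the reads a library's table accounts for, and reads fitting more than 1 gene to 0.992% to 1.48%. A gene that overlaps another, or that has an antisense partner, loses or gains counts in ways that depend on the unstated settings. The 10 most abundant genes of a library took 10.3% to 16.6% of its gene counts. No pair of replicates agreed within sampling noise: a chi-square over genes between replicates of a group was 10.9 to 68 per degree of freedom.

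Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups and a minimum count of 10, which left 13453 genes, and library sizes were scaled by TMM, with factors from 0.856 to 1.08. All 32 libraries entered a single quasi-likelihood fit (glmQLFit, glmQLFTest) with a mean for each of the 8 groups, so that all comparisons share the estimate of spread. The 14 contrasts were KO against WT in each population and diet, HFD against SD in each population and genotype, CD11c+ against CD206+ in WT on each diet, and the interactions of genotype with diet in each population and of genotype with population on each diet. P-values were adjusted by Benjamini-Hochberg within a contrast, and an adjusted p under 0.05 is called past the threshold. Expression levels are given as TMM-scaled CPM, counts scaled to a library total of 1e6, with the SD over the 4 libraries of a group, and log2 fold changes with their SE.

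Contrasts and their tests, gene lists, the rule for naming genes and, but for the block in list tests, the alternatives were fixed before the data were examined. The rule named Tnfaip3, Lyz2 and the sort and lineage genes in each contrast. In each contrast of 2 groups it named up to 10 higher and 10 lower genes with the largest fold change among those past the threshold, with at least 10 CPM on average in the higher group and no overlap between the libraries of the 2 groups. It took up to 4 members of each list with the largest change among those past the threshold, or up to 2 with the smallest p where none passed, and in interactions up to 5 genes in each direction with the smallest p. Symbols made only of clone or gene model numbers were counted and not named, and some other genes that the rule named are not reported here. Chance puts 4 libraries wholly above or below 4 others in 2.86% of divisions, so this criterion alone is weak.

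A total of 36 lists was fixed, 22 of pathways and macrophage states and 14 of markers of other cell types that the tissue or the sort could hold, and 35 had a tested member. For 3 listed symbols no gene was found in the tables. Lists were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists of a contrast. Camera compares the genes of a list with all other genes. Of 490 list tests 207 passed. With the correlation estimated for each list 11 passed, all of them among the 207. These were the lipid-associated list in CD11c+ against CD206+ WT cells on HFD, between the diets in CD206+ WT cells and between the genotypes on HFD in both populations; MHC class II in CD11c+ KO against WT cells on HFD; interferon response and MHC class I in CD206+ KO against WT cells on both diets; and fatty acid uptake and the neutrophil list in CD206+ KO against WT cells on HFD. By fry, which asks whether a list's genes move one way without comparing them with other genes, 185 passed, and 287 for movement in either direction.

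The steps were tested on counts simulated from the means and library sizes of these samples, with 200 genes changed in each of 3 draws. For KO against WT in CD11c+ cells on HFD (13290 genes tested) edgeR recovered 6.67% of genes changed 1.25-fold, 50.7% of those changed 1.5-fold, 74% at 2-fold and 97.3% at 4-fold. For HFD against SD in CD11c+ KO cells (13318 genes) it recovered 8%, 39.3%, 82.7% and 96.7%, in CD206+ KO cells (13313 genes) 7.33%, 52.7%, 82.7% and 98.7%, and for the interaction of genotype with diet in CD11c+ cells (13314 genes) 1.33%, 18.7%, 61.3% and 91.3%. Between 3.21% and 6.5% of its calls were false, against 5.04% to 8.07% by voom with quality weights and, in 1 draw each, 8% to 13.5% by DESeq2.

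Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, a stricter filter, a fit of only the compared groups, limma voom with sample quality weights, the replicate number as a block, other list tests, and leaving out each library in turn. Whether replicate numbers pair samples was checked by correlating the deviations of same-numbered libraries from their group means over the 5000 most abundant genes. Between CD11c+ and CD206+ libraries of the same genotype and diet the 4 correlations were 0.523 to 0.694 in WT HFD, 0.373 to 0.512 in WT SD and 0.311 to 0.511 in KO SD, and each of the 8 libraries in these sets correlated best with its own number. Same-numbered CD11c+ and CD206+ libraries are therefore treated as paired in these 3 sets, and the block is given beside list results where it changed a call and beside counts it moved by over 1.5 times. Its use in the list tests, with a preset or an estimated correlation, was chosen after the pairing was seen. The populations of a set being paired, overlaps between the CD11c+ and CD206+ lists of called genes are not overlaps of fully independent lists. Coordinates come from the GRCm38.p6 annotation. Some log2 fold changes of genes near 0 CPM in a group depend on the small prior count of the fit and are named with their levels.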

Results

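Macrophages were collected from the epididymal fat of C57BL/6J mice whose myeloid cells lacked A20 (KO) and of wild-type mice (WT). A20, encoded by Tnfaip3, is a ubiquitin-editing enzyme that restrains NF-kB signalling. The mice had been fed a high-fat diet (HFD) or a standard diet (SD) for 12 weeks, and 2 populations of adipose tissue macrophages were separated by flow cytometry. CD11c+ cells were low for CD206 and high for CD11c, and CD206+ cells carried the mannose receptor encoded by Mrc1. RNA was sequenced in bulk. The series asks how loss of A20 from myeloid cells bears on obesity and insulin resistance under fat-rich feeding, with the use of fatty acids by these cells as the proposed link. Genotype, diet and population made 8 groups of 4 libraries, 32 in all. Gene counts per library, in units of 1e6, summed to between 17.6 and 23.8 with a median of 20.2. Between 14314 and 15689 genes were detected in each. The labels do not say that the 4 libraries of a group came from separate mice, so p-values measure the spread between these samples, which may in part be technical.

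Tnfaip3, on chromosome 10 at 19000910 to 19015410 of GRCm38.p6, was lower in KO than in WT macrophages of both populations and on both diets. The 16 KO libraries lay between 167 and 474 CPM and the 16 WT libraries between 486 and 1647 CPM, so no KO library reached a WT one. In CD11c+ cells its level was 254 ± 79.2 CPM in KO against 693 ± 83.9 CPM in WT on HFD (SD, n = 4 each). The log2 fold change was -1.45 ± 0.20 (SE; edgeR quasi-likelihood test, adjusted p = 9.18e-07). On SD its level was 372 ± 106 against 1462 ± 128 CPM (-1.98 ± 0.20, adjusted p = 8.95e-09). In CD206+ cells Tnfaip3 stood at 213 ± 52.5 against 776 ± 92.5 CPM on HFD (-1.86 ± 0.20, adjusted p = 3.45e-08). On SD it stood at 262 ± 42.8 against 638 ± 107 CPM (-1.28 ± 0.20, adjusted p = 1.33e-05). The counts cover the whole gene, so the reads left in KO libraries do not measure how much of the allele was deleted. The genes of the sort markers followed the population labels. Itgax, which encodes CD11c (chromosome 7, 128129526 to 128150657), averaged 196 to 320.3 CPM in the 4 CD11c+ groups and 3.41 to 34.4 CPM in the 4 CD206+ groups. Mrc1 (chromosome 2, 14229414 to 14332023) averaged 453 to 633 CPM in the former and 1458 to 1893 CPM in the latter.

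**Figure D1:**
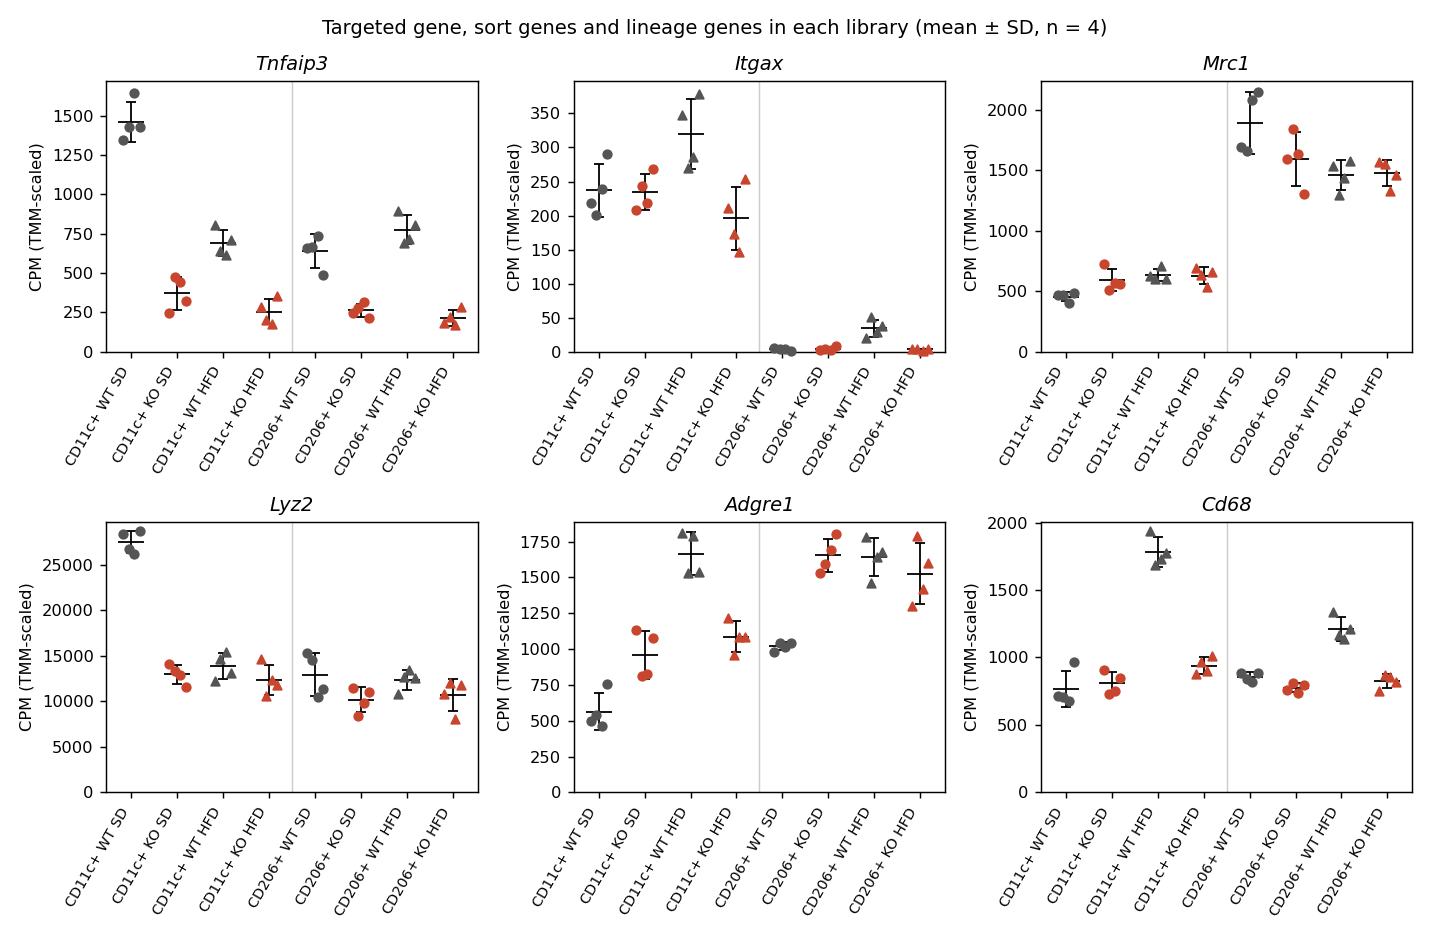
TMM-scaled CPM (y axis) of Tnfaip3, Itgax, Mrc1, Lyz2, Adgre1 and Cd68 in each of the 32 libraries, by group (x axis; grey WT, red-orange KO, circles SD, triangles HFD), with bars for the mean ± SD of 4 libraries. Tnfaip3 lies at or below 474 CPM in the KO libraries and at or above 486 CPM in the WT libraries.

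The first principal component of the log2 CPM values, with 38.3% of the variance, separated the populations. The next, with 21.2%, placed both WT HFD groups apart from the KO groups. On the third component, with 12% of the variance, the WT SD libraries stood apart from the other 24. Their mean was -51.7 ± 4.9 (SD, n = 4) in CD11c+ and -43.9 ± 4.6 in CD206+ cells, against group means of 9.5 to 28.5 elsewhere. Every comparison with a WT SD group carries this separation, which holds in both populations.

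**Figure D2:**
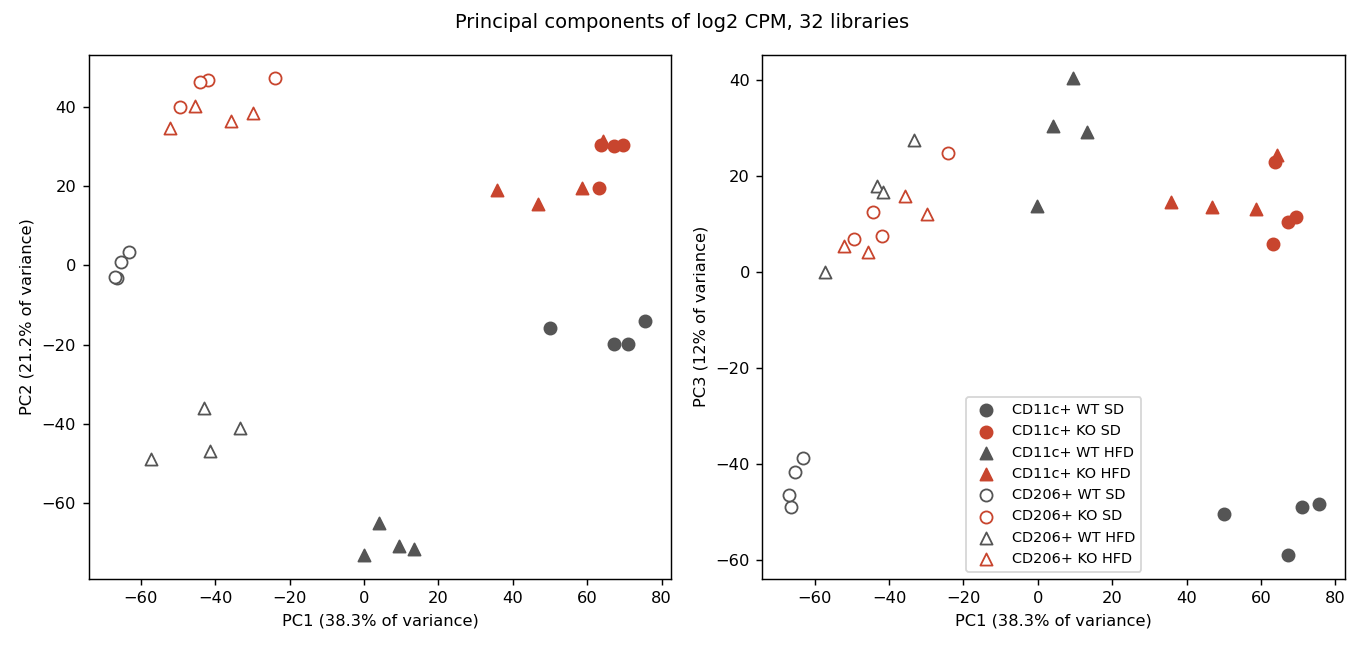
Principal components 1 and 2 (left) and 1 and 3 (right) of the log2 CPM values, 1 point per library, with the share of variance on each axis (38.3%, 21.2% and 12%), filled points for CD11c+ and open points for CD206+ libraries, coloured by genotype and shaped by diet. The 8 WT SD libraries sit apart on component 3, at group means of -51.7 and -43.9.

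The populations were first compared within WT mice. On HFD, Lyve1, a hyaluronan receptor of resident macrophages, stood at 3.37 ± 1.48 CPM in CD11c+ and 159 ± 58.4 CPM in CD206+ cells (log2 fold change -5.55 ± 0.56). The lectin Cd209f (-5.00 ± 0.58) and the carbonyl reductase Cbr2 (-4.28 ± 0.40) were also lower in CD11c+ cells. CD11c+ cells were higher for Itgax (3.22 ± 0.31), the fusion protein Dcstamp (3.79 ± 0.27) and the chemokine Ccl22 (3.51 ± 0.66). Of 32 resident and alternatively activated macrophage genes, 24 were lower and 0 higher in CD11c+ cells (24 lower and 0 higher adjusted over the list alone; median -1.53, camera adjusted p = 9.21e-19, adjusted p = 0.0726 with an estimated correlation). Of 30 genes of lipid-associated macrophages, a state described in obese fat, 24 were higher and 0 lower (26 and 1 adjusted over the list alone; median 1.01, camera adjusted p = 1.42e-18, adjusted p = 0.0422 with an estimated correlation). Markers of other cells and of handling moved with these groups, lower in CD11c+ cells for 10 of 18 stromal genes (14 adjusted over the list alone, camera adjusted p = 1.33e-07, adjusted p = 0.366 with an estimated correlation), 18 of 27 immediate early genes (21 adjusted over the list alone, camera adjusted p = 6.23e-10, adjusted p = 0.142 with an estimated correlation), 3 of 14 endothelial genes (4 adjusted over the list alone, camera adjusted p = 0.00298, adjusted p = 0.633 with an estimated correlation) and 1 of 8 mast cell genes (0 adjusted over the list alone, camera adjusted p = 0.0119, adjusted p = 0.531 with an estimated correlation). In all, 2746 of 13453 genes passed the threshold on HFD, 1575 higher and 1171 lower in CD11c+ cells.

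On SD the same contrast in WT mice called 8565 genes, 4059 higher and 4506 lower in CD11c+ cells. Lyve1 stood at 2.6 ± 1.99 CPM in CD11c+ and 395 ± 112 CPM in CD206+ cells (-7.22 ± 0.60). Dcstamp (6.25 ± 0.30), the elastase Mmp12 (6.16 ± 0.64), the chemokine Ccl17 (5.92 ± 0.69) and the chemokine receptor Ccr7 (5.14 ± 0.58) were higher in CD11c+ cells. Oxidative phosphorylation genes were higher in CD11c+ cells for 58 of 62 members and lower for 0 (60 and 0 adjusted over the list alone; median 0.74, camera adjusted p = 8.55e-19, adjusted p = 0.483 with an estimated correlation). Of 20 glycolysis genes 16 were higher and 3 lower (16 and 3 adjusted over the list alone; median 1.23, camera adjusted p = 8.58e-05, adjusted p = 0.689 with an estimated correlation). The glucose transporter Slc2a1 had a log2 fold change of 2.67 ± 0.32. Of 32 resident macrophage genes 27 were lower and 0 higher (27 and 0 adjusted over the list alone; median -3.21, camera adjusted p = 1.16e-12, adjusted p = 0.286 with an estimated correlation). Markers of other cells moved with these groups. In CD11c+ cells 15 of 16 adipocyte genes were lower (15 adjusted over the list alone; median -2.81, camera adjusted p = 0.000315, adjusted p = 0.689 with an estimated correlation). Also lower there were 14 of 14 endothelial genes (14 adjusted over the list alone; median -1.54, camera adjusted p = 0.00352, adjusted p = 0.775 with an estimated correlation). Stromal genes were lower there in 16 of 18 (with 1 higher, 16 and 1 adjusted over the list alone, camera adjusted p = 0.0117, adjusted p = 0.775 with an estimated correlation). Higher there were 11 of 18 dendritic cell genes (with 2 lower, 11 and 2 adjusted over the list alone, camera adjusted p = 0.0372, adjusted p = 0.775 with an estimated correlation). Of the genes higher in CD11c+ cells 1252 were shared between the diets, against 475.2 for independent lists, and of those lower 959, against 392.2. Same-numbered CD11c+ and CD206+ WT libraries deviated together. With the replicate number as a block in the list tests, an alternative chosen after the pairing was seen, the lipid-associated list, not called on SD (camera adjusted p = 0.0685), came to an adjusted p of 0.0407 (adjusted p = 0.633 with an estimated correlation). On HFD the block likewise brought the adipocyte (0.133 to 0.0383), mesothelial (0.318 to 0.0332), T cell (0.101 to 0.0381) and dendritic cell (0.0859 to 0.00985) lists under the threshold. With an estimated correlation beside the block none of these 4 passed (adjusted p = 0.52, 0.52, 0.59 and 0.52), and 6 lists passed on HFD: resident, lysosomal, interferon response and immediate early (each adjusted p = 0.0456), and lipid-associated and stromal (each adjusted p = 0.024).

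In WT mice, CD11c+ macrophages on HFD differed from those on SD. The fatty acid translocase Cd36 reached 5367 ± 302 CPM on HFD against 1384 ± 404 CPM on SD (1.96 ± 0.19). The scavenger receptor Msr1 rose by 2.80 ± 0.16 and the fatty acid transporter Slc27a1 by 1.91 ± 0.21. Apoe, the lipoprotein that carries cholesterol out of macrophages, rose by 2.84 ± 0.20 and the cholesterol exporter Abca1 by 2.34 ± 0.23. Gpnmb, a membrane glycoprotein of lipid-laden macrophages, went from 112 ± 51.3 to 2312 ± 562 CPM (4.37 ± 0.58). The protease Ctsk rose by 4.63 ± 0.52. Fewer transcripts came from the cytokine Il6 (9.16 ± 2.03 against 329 ± 84.5 CPM, -5.16 ± 0.43), the chemokine Ccl17 (-5.04 ± 0.64) and Retnla, a marker of alternative activation (-4.06 ± 0.46).

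By group, 26 of 30 lipid-associated macrophage genes rose and 1 fell on HFD in these CD11c+ WT cells (27 and 1 adjusted over the list alone; median 1.88, camera adjusted p = 1.13e-16, adjusted p = 0.0626 with an estimated correlation). Of 25 genes of fatty acid uptake and lipid storage 13 rose and 2 fell (15 and 2 adjusted over the list alone; median 0.62, camera adjusted p = 0.00169, adjusted p = 0.0664 with an estimated correlation). Of 42 lysosomal genes 30 rose and 2 fell (30 and 2 adjusted over the list alone; median 0.60, camera adjusted p = 5.49e-10, adjusted p = 0.223 with an estimated correlation). Against this, 48 of 62 oxidative phosphorylation genes fell and 1 rose (50 and 1 adjusted over the list alone; median -0.42, camera adjusted p = 2.52e-10, adjusted p = 0.516 with an estimated correlation). These changes were modest, such as -0.87 ± 0.09 for Uqcrfs1, a subunit of complex III. MHC class II genes fell in 12 of 15 cases and rose in 2 (12 and 2 adjusted over the list alone; median -1.10, camera adjusted p = 3.11e-06, adjusted p = 0.223 with an estimated correlation). H2-DMb2 stood at -4.37 ± 0.30. With them fell 9 of 18 dendritic cell genes (9 adjusted over the list alone, camera adjusted p = 0.000845, adjusted p = 0.516 with an estimated correlation). Monocyte genes were lower in 7 of 16 cases and higher in 3 (7 and 3 adjusted over the list alone, camera adjusted p = 0.173). NF-kB target genes fell in 21 of 34 cases and rose in 3 (22 and 3 adjusted over the list alone; median -0.61, camera adjusted p = 0.00039, adjusted p = 0.516 with an estimated correlation). Immediate early genes, which can also mark the handling of cells during isolation, fell in 19 of 27 cases (19 adjusted over the list alone; median -0.86, camera adjusted p = 2.94e-07, adjusted p = 0.3 with an estimated correlation). Stromal cell markers were higher on HFD in 14 of 18 cases and lower in 1 (15 and 1 adjusted over the list alone; median 1.90, camera adjusted p = 0.00484, adjusted p = 0.769 with an estimated correlation). The collagen gene Col1a1 was higher by 2.31 ± 0.52. Mast cell genes were higher in 6 of 8 cases (6 adjusted over the list alone; camera adjusted p = 0.178). The tryptase Tpsb2 reached 11.1 ± 5.2 CPM. In total 6234 genes differed between the diets, 3196 higher and 3038 lower on HFD.

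CD206+ macrophages of WT mice also gained lipid-associated transcripts on HFD. Gpnmb went from 4.83 ± 1.12 to 638 ± 253 CPM (7.04 ± 0.68). The secreted glycoprotein osteopontin (Spp1) rose by 5.28 ± 0.58, Mmp12 by 5.27 ± 0.62 and lipoprotein lipase (Lpl) by 2.23 ± 0.24. Itgax, the CD11c gene itself, rose by 3.23 ± 0.34 within this CD206+ gate. Retnla (831 ± 175 against 11730 ± 1120 CPM, -3.82 ± 0.46), the gelatinase Mmp9 (-4.18 ± 0.40) and the desaturase Scd1 (-3.00 ± 0.44) fell. Of the lipid-associated genes 27 of 30 rose and 0 fell (28 and 0 adjusted over the list alone; median 1.42, camera adjusted p = 6.8e-24, adjusted p = 0.0109 with an estimated correlation). Cell cycle genes rose in 30 of 44 cases and fell in 1 (32 and 1 adjusted over the list alone; median 0.76, camera adjusted p = 2.26e-09, adjusted p = 0.476 with an estimated correlation). The thymidine kinase Tk1 rose by 1.40 ± 0.22. Resident macrophage genes fell in 20 of 32 cases and rose in 1 (22 and 1 adjusted over the list alone; median -0.87, camera adjusted p = 2.26e-09, adjusted p = 0.347 with an estimated correlation). Of 51 interferon response genes 21 fell and 0 rose (24 and 1 adjusted over the list alone; median -0.49, camera adjusted p = 1.57e-05, adjusted p = 0.578 with an estimated correlation). Adipocyte markers were lower on HFD in 14 of 16 cases (15 adjusted over the list alone; median -2.26, camera adjusted p = 4.27e-09, adjusted p = 0.15 with an estimated correlation). The adipokine Cfd had a log2 fold change of -5.13 ± 0.53. Stromal markers were higher in 10 of 18 cases (14 adjusted over the list alone; median 1.21, camera adjusted p = 4.01e-05, adjusted p = 0.572 with an estimated correlation). Immediate early genes were lower in 15 of 27 (18 adjusted over the list alone; median -0.77, camera adjusted p = 5.74e-06, adjusted p = 0.418 with an estimated correlation). Mast cell genes were higher in 6 of 8 (6 adjusted over the list alone, camera adjusted p = 0.0113, adjusted p = 0.573 with an estimated correlation). Tpsb2 stood at 31.5 ± 19.1 CPM on HFD and 2.18 ± 1.27 CPM on SD. Lower were 7 of 18 dendritic cell genes (7 adjusted over the list alone, camera adjusted p = 0.00574, adjusted p = 0.573 with an estimated correlation) and 1 of 14 endothelial genes (1 adjusted over the list alone, camera adjusted p = 0.000653, adjusted p = 0.573 with an estimated correlation). A total of 3728 genes differed, 1916 higher and 1812 lower on HFD. With the CD11c+ lists they shared 1048 higher genes (455.2 for independent lists) and 761 lower ones (409.2), while 395 moved in opposite directions.

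Loss of A20 on HFD was the central comparison. In CD11c+ macrophages several single transcripts rose by very large factors. The acute-phase protein Saa3 averaged 356 ± 162 CPM in KO and 0.628 ± 0.342 CPM in WT (9.14 ± 0.66). Irg1, the enzyme that makes itaconate, averaged 221 ± 100 against 1.3 ± 1.23 CPM (7.41 ± 0.75). Complement factor B (Cfb) rose by 6.07 ± 0.31, and the chemokines Ccl5 and Cxcl13 by 5.24 ± 0.32 and 5.12 ± 0.63. Cd36 stood at 1610 ± 371 CPM in KO against 5367 ± 302 CPM in WT (-1.74 ± 0.19) and Lpl at 2135 against 6412 CPM (-1.59 ± 0.24). Mgll, which releases fatty acids from monoglycerides, fell by 2.00 on the log2 scale. Gpnmb (251 against 2312 CPM, -3.20 ± 0.55), Ctsk (-3.85 ± 0.49), the vacuolar ATPase subunit Atp6v0d2 (-3.35 ± 0.35) and carboxypeptidase E (Cpe, -6.56 ± 0.35) were also lower in KO cells. For the genes named by size here, the lack of overlap between the 4 KO and 4 WT libraries was a condition of naming and not a separate result.

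Interferon response genes rose in 49 of 51 cases in these CD11c+ HFD cells and fell in 0 (51 and 0 adjusted over the list alone; median 2.04, camera adjusted p = 6.42e-32, adjusted p = 0.0517 with an estimated correlation). Iigp1, a guanosine triphosphatase induced by interferon, rose by 3.93 ± 0.42. MHC class II genes rose in 15 of 15 (15 adjusted over the list alone; median 1.03, camera adjusted p = 5.33e-12, adjusted p = 0.0379 with an estimated correlation). The co-stimulatory receptor Cd40 rose by 1.71 ± 0.17. MHC class I genes rose in 17 of 18 (18 adjusted over the list alone; median 1.29, camera adjusted p = 4.03e-17, adjusted p = 0.0517 with an estimated correlation). The peptide transporter Tap1 rose by 2.24 ± 0.25. Targets of NF-kB rose in 19 of 34 cases and fell in 2 (20 and 2 adjusted over the list alone; median 0.44, camera adjusted p = 4.46e-06, adjusted p = 0.198 with an estimated correlation). The lectin receptor Clec4e rose by 3.86 ± 0.34. Cytokines and chemokines rose in 27 of 38 and fell in 3 (28 and 4 adjusted over the list alone; median 1.22, camera adjusted p = 1.91e-06, adjusted p = 0.0888 with an estimated correlation). Oxidative phosphorylation genes rose in 54 of 62 cases and fell in 1 (58 and 1 adjusted over the list alone; median 0.43, camera adjusted p = 6.33e-17, adjusted p = 0.194 with an estimated correlation). The amounts were modest, such as 0.76 ± 0.10 for Cox5a. Glycolysis genes rose in 14 of 20 cases and fell in 1 (14 and 1 adjusted over the list alone; median 0.54, camera adjusted p = 5.88e-05, adjusted p = 0.253 with an estimated correlation). The lactate exporter Slc16a3 rose by 2.12 ± 0.30. Lipid-associated macrophage genes fell in 26 of 30 cases and rose in 0 (27 and 0 adjusted over the list alone; median -1.41, camera adjusted p = 1.37e-16, adjusted p = 0.0379 with an estimated correlation).

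Markers of other cells moved along with these groups in the CD11c+ HFD contrast. T cell genes were higher in KO libraries for 17 of 19 members (17 adjusted over the list alone; median 2.90, camera adjusted p = 2.69e-05, adjusted p = 0.361 with an estimated correlation). Cd3e was higher by 3.41 ± 0.66. Monocyte genes were higher for 12 of 16 and lower for 1 (12 and 2 adjusted over the list alone; median 2.02, camera adjusted p = 8.6e-06, adjusted p = 0.134 with an estimated correlation). Dendritic cell genes, several of which activated macrophages also make, were higher beside the MHC class II genes for 16 of 18 (16 adjusted over the list alone; median 1.55, camera adjusted p = 8.6e-06, adjusted p = 0.198 with an estimated correlation). The integrin Itgae was higher by 3.49 ± 0.77. Higher as well were 8 of 9 natural killer cell genes (8 adjusted over the list alone, camera adjusted p = 0.00127, adjusted p = 0.198 with an estimated correlation), 6 of 9 neutrophil genes (6 adjusted over the list alone, camera adjusted p = 0.00129, adjusted p = 0.0772 with an estimated correlation) and 12 of 27 immediate early genes (with 1 lower, 12 and 1 adjusted over the list alone, camera adjusted p = 0.00284, adjusted p = 0.451 with an estimated correlation). Stromal genes were lower in KO for 16 of 18 and higher for 1 (16 and 1 adjusted over the list alone; median -2.47, camera adjusted p = 3.4e-05, adjusted p = 0.378 with an estimated correlation). Col3a1 averaged 29 CPM in KO and 178 CPM in WT. In total 5116 of 13453 genes passed the threshold, 2504 higher and 2612 lower in KO, of which 1921 changed at least 2-fold. The WT HFD libraries enter both this contrast and that between the diets in WT, so opposite signs in the 2 contrasts are not independent observations.

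CD206+ macrophages on HFD showed a related change without A20. Saa3 rose to 949 ± 226 CPM from 7.56 ± 5.39 CPM (6.98 ± 0.54). Irg1 rose by 6.53 ± 0.71, Ccl5 by 5.39 ± 0.32 and Cxcl13 from 24 to 483 CPM (4.34 ± 0.52). Gpnmb (23.3 against 638 CPM, -4.78 ± 0.60), Mmp12 (-4.60 ± 0.59), Spp1 (-4.25 ± 0.54), Lpl (-1.90 ± 0.24), the fatty acid binding protein Fabp5 (-1.96 ± 0.25) and Itgax (-3.34 ± 0.34) fell. Interferon response genes rose in 50 of 51 cases (51 adjusted over the list alone; median 1.85, camera adjusted p = 2.27e-48, adjusted p = 0.0165 with an estimated correlation). MHC class I genes rose in 17 of 18 (17 adjusted over the list alone; median 1.29, camera adjusted p = 1.1e-23, adjusted p = 0.0165 with an estimated correlation). MHC class II genes rose in 11 of 15 (13 adjusted over the list alone; median 0.60, camera adjusted p = 6.21e-08, adjusted p = 0.0653 with an estimated correlation). Lipid-associated genes fell in 22 of 30 cases (25 adjusted over the list alone; median -1.12, camera adjusted p = 4.62e-21, adjusted p = 0.0165 with an estimated correlation). Cell cycle genes fell in 25 of 44 cases and rose in 0 (31 and 1 adjusted over the list alone; median -0.64, camera adjusted p = 3e-09, adjusted p = 0.312 with an estimated correlation). The kinesin Kif11 had a log2 fold change of -1.15 ± 0.24. Beside these groups, T cell genes were higher in KO for 17 of 19 members (18 adjusted over the list alone; median 2.60, camera adjusted p = 1.86e-08, adjusted p = 0.205 with an estimated correlation). Cd4 averaged 57.3 against 4.45 CPM. Adipocyte genes were higher for 10 of 16 (11 adjusted over the list alone; median 1.52, camera adjusted p = 2.77e-05, adjusted p = 0.205 with an estimated correlation). All 18 stromal genes were lower (18 adjusted over the list alone; median -2.30, camera adjusted p = 3.84e-12, adjusted p = 0.144 with an estimated correlation). Neutrophil genes were higher for 6 of 9 (6 adjusted over the list alone, median 2.43, camera adjusted p = 0.000109, adjusted p = 0.0295 with an estimated correlation). S100a8 and S100a9 lay near the floor (1.09 against 0.199 and 1.035 against 0.154 CPM). The most abundant members were Mmp9 (760 against 21.9 CPM) and Csf3r (87.7 against 39.5 CPM), given without TMM scaling. On that scale Mmp9 stood at 394.8 CPM in CD206+ WT SD cells, so it need not come from neutrophils. Higher as well were 9 of 16 monocyte genes (10 adjusted over the list alone, camera adjusted p = 2.14e-05, adjusted p = 0.144 with an estimated correlation), 3 of 9 natural killer cell genes (5 adjusted over the list alone, camera adjusted p = 0.0219, adjusted p = 0.411 with an estimated correlation) and 6 of 27 immediate early genes (7 adjusted over the list alone, camera adjusted p = 0.00822, adjusted p = 0.541 with an estimated correlation). The mesothelial list was called with 0 of 9 members called (median 1.43, camera adjusted p = 0.0177, adjusted p = 0.541 with an estimated correlation). Lower were 1 of 8 mast cell genes (6 adjusted over the list alone, camera adjusted p = 0.00657, adjusted p = 0.411 with an estimated correlation). The count was 2930 genes, 1408 higher and 1522 lower in KO. Of these, 1061 higher and 1105 lower genes were shared with the CD11c+ contrast, against 262.1 and 295.5 for independent lists. A further 22 moved in opposite directions.

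Loss of A20 was next compared on SD. In CD11c+ macrophages Saa3 averaged 251 ± 116 CPM in KO and 0.281 ± 0.393 CPM in WT (9.69 ± 0.71). The scavenger receptor Marco rose by 5.90 ± 1.03, Cfb by 6.05 ± 0.31 and haptoglobin (Hp) by 5.16 ± 0.42. In CD206+ macrophages Irg1 rose by 7.44 ± 0.73, Ccl5 from 1.58 to 133 CPM (6.37 ± 0.35) and Clec4e by 4.14 ± 0.34. The lectin Cd209b fell from 179.5 to 5.65 CPM (-4.99 ± 0.50), and the iron exporter Slc40a1 fell by 3.77 ± 0.55. Interferon response genes rose in 48 of 51 cases in CD11c+ cells (50 adjusted over the list alone; median 2.17, camera adjusted p = 4.73e-47, adjusted p = 0.0553 with an estimated correlation). The transcription factor Irf7 rose there by 3.98 ± 0.25. In CD206+ cells 48 interferon response genes rose (50 adjusted over the list alone; median 1.57, camera adjusted p = 1.26e-46, adjusted p = 0.0291 with an estimated correlation). NF-kB target genes rose in 24 of 34 in CD206+ cells and fell in 3 (24 and 4 adjusted over the list alone; median 0.68, camera adjusted p = 2.01e-11, adjusted p = 0.116 with an estimated correlation). In CD11c+ cells 16 rose and 11 fell (16 and 11 adjusted over the list alone; median 0.26, camera adjusted p = 0.0189, adjusted p = 0.709 with an estimated correlation).

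Lipid-associated genes did not move as a group on SD. In CD11c+ cells 9 rose and 4 fell (11 and 5 adjusted over the list alone; camera adjusted p = 0.214). In CD206+ cells 4 rose and 6 fell (4 and 6 adjusted over the list alone; camera adjusted p = 0.919). Msr1 rose by 2.07 ± 0.16 and the nuclear receptor Nr1h3 (LXR alpha) by 2.19 ± 0.19 in CD11c+ KO cells, whereas the fatty acid binding protein Fabp4 fell by 1.72 ± 0.33. Lysosomal genes rose in 20 of 42 cases and fell in 1 in CD11c+ cells (24 and 1 adjusted over the list alone; median 0.28, camera adjusted p = 1.09e-05, adjusted p = 0.633 with an estimated correlation). Resident macrophage genes fell in 14 of 32 and rose in 2 in CD206+ cells (14 and 2 adjusted over the list alone; median -0.56, camera adjusted p = 2.18e-05, adjusted p = 0.436 with an estimated correlation). Endothelial markers were lower in KO on SD for 10 of 14 genes in CD11c+ cells (11 adjusted over the list alone; median -1.68, camera adjusted p = 0.00281, adjusted p = 0.709 with an estimated correlation). In CD206+ cells 13 were lower (13 adjusted over the list alone; median -1.65, camera adjusted p = 1.74e-07, adjusted p = 0.428 with an estimated correlation). Immediate early genes were lower in CD11c+ KO cells for 13 of 27 and higher for 3 (18 and 4 adjusted over the list alone; median -0.52, camera adjusted p = 0.00113, adjusted p = 0.633 with an estimated correlation). T cell genes were higher for 11 and lower for 2 in CD206+ KO cells (13 and 2 adjusted over the list alone; median 2.04, camera adjusted p = 0.003, adjusted p = 0.549 with an estimated correlation). Monocyte genes were higher in KO for 10 of 16 and lower for 2 in CD11c+ cells (10 and 3 adjusted over the list alone, camera adjusted p = 0.00774, adjusted p = 0.633 with an estimated correlation) and higher for 10 and lower for 1 in CD206+ cells (10 and 1 adjusted over the list alone, camera adjusted p = 0.000764, adjusted p = 0.428 with an estimated correlation). Lower in CD206+ KO cells were 9 of 18 stromal genes (10 adjusted over the list alone, camera adjusted p = 0.00298, adjusted p = 0.549 with an estimated correlation) and 5 of 16 adipocyte genes (with 1 higher, 5 and 1 adjusted over the list alone, camera adjusted p = 0.0109, adjusted p = 0.549 with an estimated correlation). The counts on SD were 3607 genes in CD11c+ cells (1775 higher, 1832 lower in KO) and 3300 in CD206+ cells (1594 higher, 1706 lower). The populations shared 873 higher and 768 lower genes, against 210.3 and 232.3 for independent lists. Between the diets, the CD11c+ contrasts shared 705 higher and 481 lower genes (330.4 and 355.7 for independent lists) and 731 moved in opposite directions. The CD206+ contrasts shared 673 and 454 (166.8 and 193) with 152 opposite.

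Between the diets, KO macrophages differed far less than WT macrophages in the number of genes called. In CD11c+ cells edgeR called 1 gene, with 1221 genes at an unadjusted p under 0.05. DESeq2 called 51 and voom with quality weights 1. Without KO HFD replicate 1 the count was 80, without replicate 4 16, without replicate 2 2 and without replicate 3 0. Without KO SD replicate 1 it was 3, and without KO SD replicates 2 or 3 it was 0. In CD206+ cells edgeR called 0 genes, with 831 at an unadjusted p under 0.05, against 18 by DESeq2 and 0 by voom. In simulated counts for these contrasts 9.77% (CD11c+) and 11% (CD206+) of the calls by DESeq2 were false, against 5.82% and 3.21% by edgeR. The count was 7 without KO SD replicate 1, 2 without KO SD replicate 4 and 1 without KO HFD replicate 3. The lipid droplet protein Plin2 stood at 1634 ± 222 CPM on HFD and 896 ± 203 CPM on SD in CD11c+ KO cells (adjusted p = 0.116). The fatty acid synthase Fasn stood at 18 ± 3.43 and 46.5 ± 21.5 CPM in CD206+ KO cells (adjusted p = 0.0966).

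Small shifts of whole groups between the diets in KO cells did pass the list test at the preset correlation. These were 19 of 35 lists in CD11c+ and 21 of 35 in CD206+ cells. With an estimated correlation 0 passed in either population. By fry 2 of the 19 and 1 of the 21 passed in the same direction. Cholesterol synthesis genes had a median log2 fold change of -0.60 in CD11c+ cells (camera adjusted p = 4.4e-22, adjusted p = 0.0861 with an estimated correlation). Over all genes 0 of 22 were called, and 19 were lower adjusted over the list alone. Lipid-associated genes had a median of 0.44 there (camera adjusted p = 1.55e-11, adjusted p = 0.0861 with an estimated correlation). There were 0 called over all genes, and 15 higher and 1 lower adjusted over the list alone. Interferon response genes had a median of -0.42 in CD206+ cells (camera adjusted p = 4.33e-26, adjusted p = 0.166 with an estimated correlation). Of its members 0 were called over all genes and 2 were lower adjusted over the list alone. T cell genes were at a median of 0.85 in the same contrast (camera adjusted p = 1.46e-06, adjusted p = 0.366 with an estimated correlation; 0 called over all genes, 0 higher adjusted over the list alone). Other lists of cell types and handling called in KO cells had 0 members called over all genes. In CD11c+ cells these were neutrophil (median 1.47, camera adjusted p = 0.000312, adjusted p = 0.0861 with an estimated correlation), B cell (median 0.61, camera adjusted p = 0.00139, adjusted p = 0.343 with an estimated correlation), T cell (median 0.32, camera adjusted p = 0.0174, adjusted p = 0.697 with an estimated correlation) and immediate early genes (median -0.10, camera adjusted p = 0.0342, adjusted p = 0.697 with an estimated correlation). In CD206+ cells they were neutrophil (median 0.84, camera adjusted p = 0.0214, adjusted p = 0.304 with an estimated correlation), B cell (median 0.93, camera adjusted p = 0.0232, adjusted p = 0.623 with an estimated correlation), endothelial (median 0.35, camera adjusted p = 0.03, adjusted p = 0.662 with an estimated correlation) and immediate early genes (median -0.13, camera adjusted p = 0.0222, adjusted p = 0.626 with an estimated correlation).

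The interaction of genotype with diet, which tests whether the KO effect on HFD differed from that on SD, called 3877 genes in CD11c+ cells (1864 higher, 2013 lower) and 1595 in CD206+ cells (703 higher, 892 lower). Lipid-associated genes had lower interaction values in 24 of 30 cases in CD11c+ cells (25 adjusted over the list alone; median -1.46, camera adjusted p = 4.87e-16, adjusted p = 0.0745 with an estimated correlation). In CD206+ cells 21 had lower values (22 adjusted over the list alone; median -1.16, camera adjusted p = 5.93e-17, adjusted p = 0.0567 with an estimated correlation). The scavenger receptor Msr1 had an interaction of -2.70 ± 0.22 in CD11c+ cells and Itgax of -3.64 ± 0.50 in CD206+ cells, on the log2 scale. MHC class II genes had higher interaction values in 12 of 15 cases and lower in 1 in CD11c+ cells (12 and 1 adjusted over the list alone; median 1.09, camera adjusted p = 3.98e-07, adjusted p = 0.215 with an estimated correlation). Oxidative phosphorylation genes had higher values in 37 of 62 and lower in 1 (42 and 2 adjusted over the list alone; median 0.41, camera adjusted p = 7.56e-10, adjusted p = 0.555 with an estimated correlation). In CD206+ cells 15 of 32 resident macrophage genes had higher values (18 adjusted over the list alone; median 1.19, camera adjusted p = 4.89e-11, adjusted p = 0.29 with an estimated correlation). Beside them 8 of 16 adipocyte genes had higher values (14 adjusted over the list alone; median 2.16, camera adjusted p = 1.25e-10, adjusted p = 0.13 with an estimated correlation). Values were also higher in CD11c+ cells for 15 of 27 immediate early genes (16 adjusted over the list alone, camera adjusted p = 1.65e-06, adjusted p = 0.394 with an estimated correlation), 8 of 18 dendritic cell genes (8 adjusted over the list alone, camera adjusted p = 0.000204, adjusted p = 0.555 with an estimated correlation), 4 of 19 T cell genes (2 adjusted over the list alone, camera adjusted p = 0.016, adjusted p = 0.79 with an estimated correlation) and 4 of 9 natural killer cell genes (4 adjusted over the list alone, camera adjusted p = 0.0221, adjusted p = 0.555 with an estimated correlation). In CD206+ cells they were higher for 6 of 27 immediate early genes (8 adjusted over the list alone, camera adjusted p = 0.000363, adjusted p = 0.554 with an estimated correlation), 5 of 18 dendritic cell genes (6 adjusted over the list alone, camera adjusted p = 0.015, adjusted p = 0.618 with an estimated correlation) and 1 of 14 endothelial genes (1 adjusted over the list alone, camera adjusted p = 0.000218, adjusted p = 0.554 with an estimated correlation). They were lower there for 4 of 18 stromal genes (6 adjusted over the list alone, camera adjusted p = 0.000998, adjusted p = 0.618 with an estimated correlation). Both interactions include the WT SD libraries that stood apart on the third principal component.

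The interaction of genotype with population asked whether the KO effect differed between CD11c+ and CD206+ cells. It called 586 genes on HFD (290 higher, 296 lower) and 884 on SD (551 higher, 333 lower). On HFD, Itgax had a value of 2.63 ± 0.44, the protease Adam8 2.35 ± 0.33 and the uridine-cytidine kinase Uck2 2.35 ± 0.36. Cell cycle genes had higher values in 8 of 44 cases (32 adjusted over the list alone; median 0.75, camera adjusted p = 2.39e-18, adjusted p = 0.44 with an estimated correlation). Lists of other cells called there were dendritic cell (median 0.92, camera adjusted p = 0.0153, adjusted p = 0.84 with an estimated correlation), monocyte (median 0.85, camera adjusted p = 0.0245, adjusted p = 0.84 with an estimated correlation) and adipocyte genes (median -0.95, camera adjusted p = 0.0245, adjusted p = 0.84 with an estimated correlation). On SD, the transcription factors Tfec and Maf had values of 3.25 ± 0.31 and 1.69 ± 0.19, the nuclear receptor Nr4a2 -2.16 ± 0.32 and the niacin receptor Hcar2 -2.78 ± 0.42. Of 32 resident macrophage genes 11 had higher values (13 adjusted over the list alone; median 1.05, camera adjusted p = 2.25e-07, adjusted p = 0.807 with an estimated correlation). The NF-kB target list was called there with lower values (camera adjusted p = 2.1e-06). Called with higher values were the cell cycle (camera adjusted p = 1.19e-05), interferon response (0.000342) and lipid-associated lists (0.0432). With an estimated correlation 0 of the 35 lists passed on SD. With the replicate number as a block the counts were 1209 on HFD, where pairing of the KO libraries was unresolved, and 1612 on SD. With the block in the list tests on SD, MHC class I (0.0695 to 0.0306), lysosomal (0.0695 to 0.0306), inflammasome (0.0719 to 0.0395), immediate early (0.0719 to 0.0202) and adipocyte (0.0709 to 0.017) lists came under the threshold and oxidative phosphorylation left it (0.0432 to 0.0618). With an estimated correlation beside the block 0 lists passed there (adjusted p = 0.644 to 0.648 for the 5 gained and adjusted p = 0.791 for oxidative phosphorylation). With only the compared groups fitted, 50.3% of the called genes were higher against 62.3%. The HFD count fell to 354 without CD11c+ KO HFD replicate 2, to 306 without CD206+ KO HFD replicate 3 and to 316 without CD11c+ WT HFD replicate 1.

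Fatty acid metabolism was followed across all genotype contrasts. Of the genes of mitochondrial fatty acid oxidation, more fell than rose in KO cells in each of the 4 contrasts, and the list test called the group in 1 of them. Of all genes 21.8% to 38% were called there, so these counts alone do not single out the list. In CD206+ cells 8 of 23 fell and 0 rose on SD (8 and 0 adjusted over the list alone; median -0.22, camera adjusted p = 0.00187, adjusted p = 0.428 with an estimated correlation). On HFD 6 fell and 0 rose (6 and 0 adjusted over the list alone; camera adjusted p = 0.063). In CD11c+ cells 6 fell and 3 rose on HFD (6 and 4 adjusted over the list alone; camera adjusted p = 0.609). On SD 5 fell and 2 rose (5 and 2 adjusted over the list alone; camera adjusted p = 0.106). The peroxisomal oxidation and fatty acid synthesis lists were called in no genotype contrast. On HFD the trifunctional protein subunits Hadha and Hadhb, of the later steps of beta-oxidation, fell in KO cells. Their log2 fold changes were -0.66 ± 0.08 and -0.55 ± 0.07 in CD11c+ cells and -0.63 ± 0.08 and -0.52 ± 0.07 in CD206+ cells. On SD Pdk4, a kinase that blocks pyruvate oxidation and so favours fatty acids as fuel, fell by 1.96 ± 0.56 in CD11c+ cells and fell by 2.25 ± 0.51 in CD206+ cells (9.1 against 43.5 CPM).

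Genes of fatty acid uptake and lipid storage fell in KO cells on HFD in 14 of 25 cases and rose in 1 in CD11c+ cells (14 and 1 adjusted over the list alone; median -0.49, camera adjusted p = 0.00213, adjusted p = 0.0517 with an estimated correlation). In CD206+ cells 12 fell and 2 rose (13 and 2 adjusted over the list alone; median -0.45, camera adjusted p = 0.00121, adjusted p = 0.0295 with an estimated correlation). On SD the list went both ways, with 5 up and 6 down in CD11c+ cells (5 and 7 adjusted over the list alone; camera adjusted p = 0.974). In CD206+ cells 5 were up and 8 down (6 and 9 adjusted over the list alone; camera adjusted p = 0.406). As a group, mitochondrial oxidation genes were not called in the interaction of genotype with diet (camera adjusted p = 0.549 in CD11c+ and 0.298 in CD206+ cells). Of the single genes above, the interaction was called for Hadha in CD11c+ cells (-0.55 ± 0.11) and in CD206+ cells (-0.52 ± 0.11), and in CD206+ cells for Hadhb (-0.52 ± 0.10) and for Pdk4 (2.25 ± 0.70, adjusted p = 0.0336, not called when any of 7 single libraries was left out). Transcript levels are not rates of oxidation, and flux, protein and body weight were not analysed here.

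**Figure D3:**
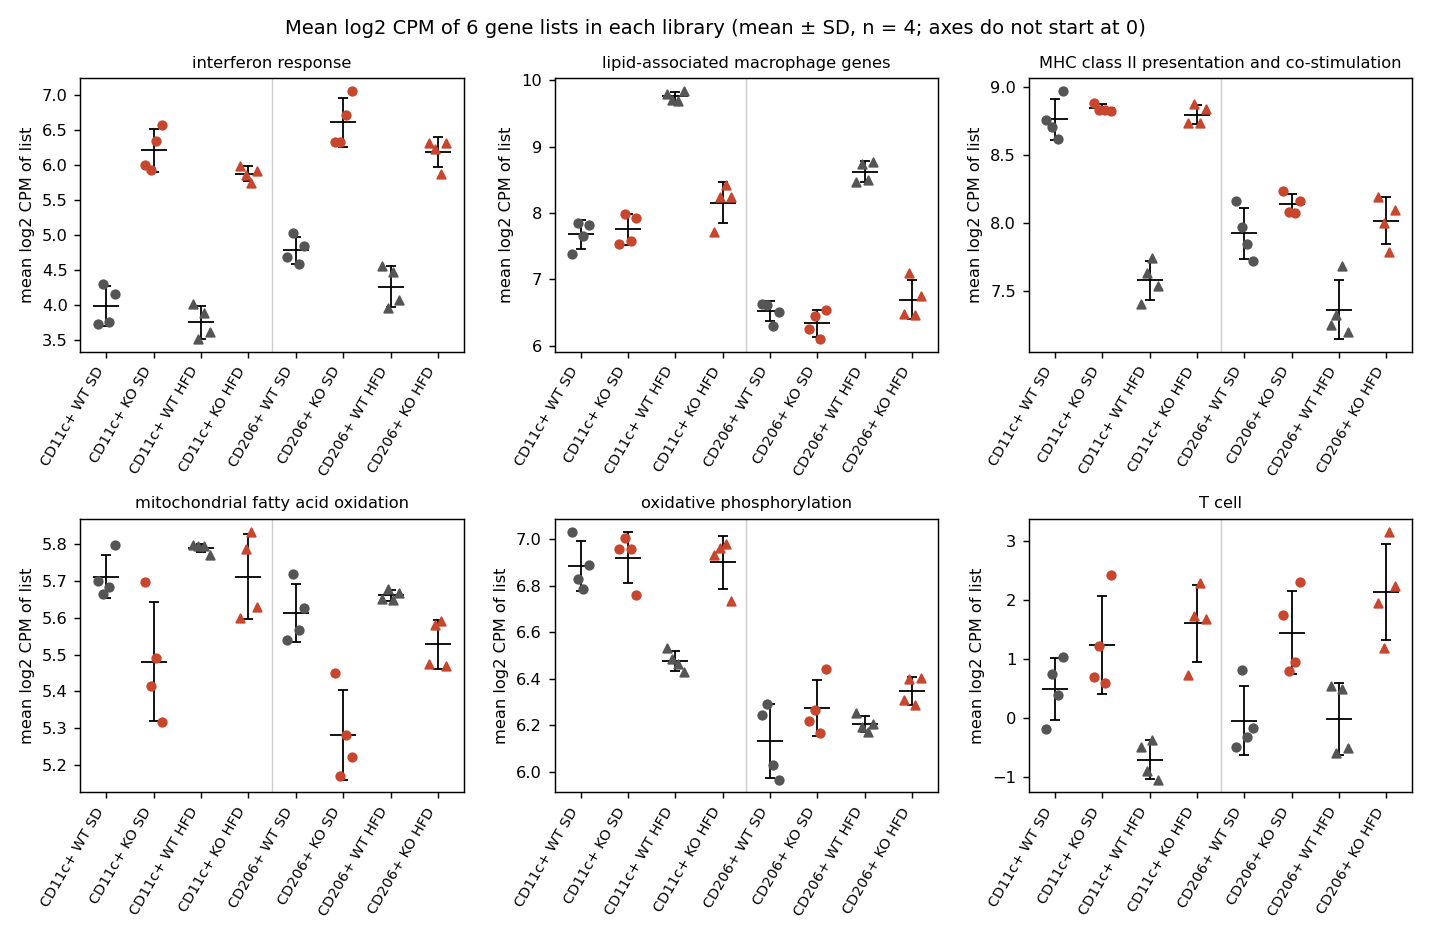
Mean log2 CPM over the tested members (y axis) of 6 gene lists in each library, by group (x axis; grey WT, red-orange KO, circles SD, triangles HFD), with bars for the mean ± SD of 4 libraries. The lipid-associated list mean of the WT HFD libraries lies at or above 9.692 in CD11c+ and 8.471 in CD206+ cells, while no KO library exceeds 8.429 and 7.096.

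**Figure D4:**
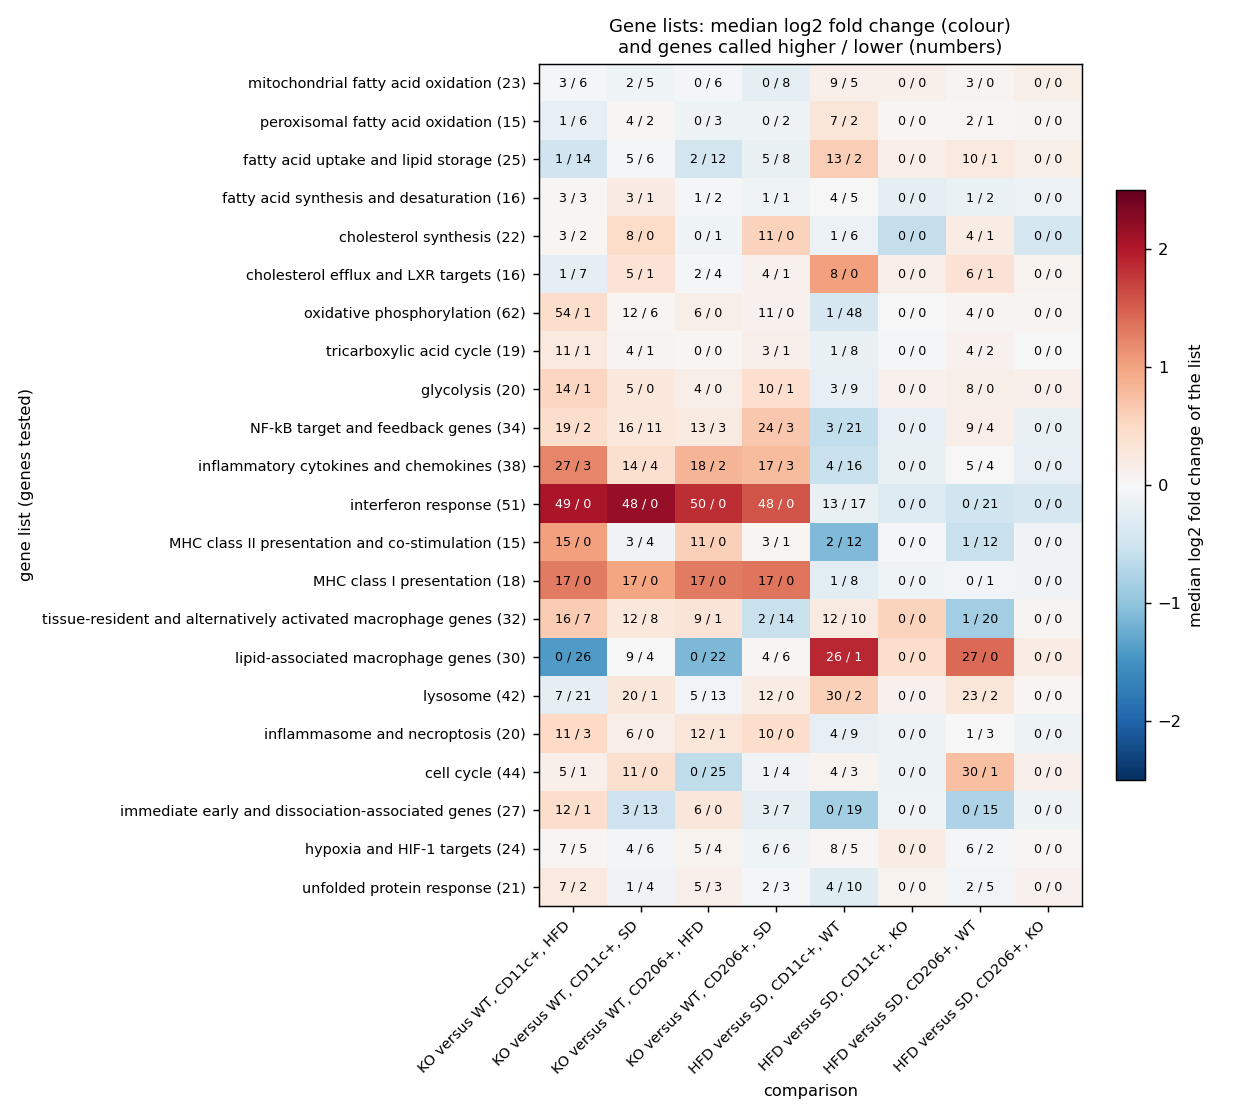
Median log2 fold change (colour) of the 22 pathway lists (vertical axis) in 8 contrasts of genotype and diet (horizontal axis), with the numbers of members called higher and lower at an adjusted p under 0.05 written in each cell. For interferon response genes the 4 genotype contrasts show 48 to 50 of 51 members higher in KO, and the diet contrasts in KO show 0 called members.

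Several genes named here belong to families with near-identical copies, among them Cd209, Fpr, Ly6, Gbp, H2-Q, Saa, Ear and mast cell protease genes and the pair Lyz1 and Lyz2. How reads shared between such copies were counted is not given in the sources used here, so the values of single members are uncertain. Lyz2, whose promoter drives Cre in a widely used myeloid deleter strain (the strain used is not given in the sources used here), averaged 27500 ± 1210 CPM in CD11c+ WT SD cells and 12970 ± 1060 CPM in CD11c+ KO SD cells (-1.08 ± 0.13, adjusted p = 2.25e-07). On HFD it averaged 12330 ± 1680 CPM in KO against 13870 ± 1450 CPM in WT (adjusted p = 0.322). The pan-macrophage gene Adgre1 (F4/80) was lower in CD11c+ KO cells on HFD (-0.62 ± 0.13, adjusted p = 0.00028) and higher on SD (0.77 ± 0.13, adjusted p = 3.06e-05), with an interaction of -1.39 ± 0.18 (adjusted p = 8.47e-07).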

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

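Chosen only after the result was seen were the tests of the KO diet slope, of mixed diet labels, of a shared shift in the WT SD libraries, of a rise of all non-macrophage RNA alike, of reads moving between Lyz1 and Lyz2, and of divisions by the pairs they part or keep; the T cell correlation, the window around the targeted loci and all counts over other divisions of the libraries were set before.

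The effect of genotype differed between the diets by a test of the interaction itself, for 3877 genes in CD11c+ and 1595 in CD206+ cells. In CD11c+ cells the log2 interaction was 0.91 for Lyz2, -1.39 for Adgre1, -0.51 for Csf1r and -1.003 for Cd68. Among the genes with the smallest p it was 3.16 for Tspan32, 1.87 for Ahcyl2, 3.495 for Lilra6, 4.30 for Hepacam2, 2.29 for Pilrb2, -2.15 for Rhoc, -2.31 for Rasa1, -3.95 for Hpgds, -1.43 for Tnfaip1 and -2.70 for Msr1. In CD206+ cells it was -3.64 for Itgax, -0.80 for Adgre1 and -0.41 for Cd68. Among the genes with the smallest p there it was 1.33 for Trappc5, 2.06 for Tspan32, 3.66 for Dnase1l3, 1.38 for Abcg3, 1.98 for Rtn1, -2.27 for Tlr13, -2.07 for Glipr1 and -3.39 for Plxdc1. The effect of genotype also differed between the populations, for 586 genes on HFD and 884 on SD. On HFD the log2 interaction was 2.63 for Itgax, 2.1 for Slc9a4, 2.35 for Adam8, 2.35 for Uck2, 2.40 for Chn2, 1.96 for Mboat1, -1.13 for Pls3, -1.97 for Dlg3, -2.02 for Clstn1, -2.59 for Rasgrp3 and -1.58 for Plscr4. On SD it was -0.74 for Lyz2, 0.63 for Mrc1, 0.69 for Csf1r, 3.25 for Tfec, 1.77 for Fam213b, 1.69 for Maf, 2.08 for Aoah, 1.43 for Clmp, -2.16 for Nr4a2, -1.99 for Slc13a3, -2.78 for Hcar2, -1.60 for Cd52 and -0.95 for Bid.

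A single library stood far from the other 3 of its group in 4 of 80 groups of values tested, about the 1 in 20 that chance gives. These were Lyz1 in CD11c+ WT SD replicate 2 (5630 CPM, mean of the others 10920), Itgam in CD11c+ WT HFD replicate 4 (771 against 560.1), and Csf1r and Cd68 in CD11c+ WT SD replicate 4 (2424 against 1553, and 966.7 against 698.4). Among reads left out of the gene counts, the share fitting more than 1 gene was higher in KO than in WT libraries in all 4 pairs of groups: 1.428% against 1.204% in CD11c+ and 1.292% against 1.116% in CD206+ cells on HFD, and 1.401% against 1.220% and 1.246% against 1.046% on SD. Reads outside genes were 8.788% in KO and 7.921% in WT in CD206+ cells on HFD. Each of these 5 had an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 libraries allow, and an adjusted p of 0.0458 over 8 tests. The other 3 comparisons of reads outside genes went both ways and did not pass: 6.598% in KO against 6.339% in WT in CD11c+ cells on HFD (adjusted p = 0.771), 6.295% against 7.094% in CD11c+ cells on SD (adjusted p = 0.195) and 9.311% against 10.42% in CD206+ cells on SD (adjusted p = 0.152). Which genes the reads fitting more than 1 gene overlap was not analysed here.

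In KO macrophages 1 gene (CD11c+) and 0 genes (CD206+) passed the threshold between the diets by edgeR, against 6234 and 3728 in WT, with 1221 and 831 KO genes at an unadjusted p under 0.05 and 51 and 18 calls by DESeq2. Some values argue against technical explanations, with limits given below. Over the genes called in WT the slope of the KO on the WT diet change was 0.113 (SE 0.041) in CD11c+ and 0.048 (SE 0.056) in CD206+ cells. Both are far under the 1 that a WT-sized response hidden by noise would give. Of these genes 68.8% and 58.3% had the WT sign, however (correlation over genes 0.397 and 0.17). Mixed diet labels over a WT-sized response would spread the KO libraries along the lipid-associated list as widely as the WT diets. Their range was 0.431 (CD11c+) and 0.475 (CD206+) of the WT gap. With a smaller response mixed labels would give a narrow range too, so the range cannot tell whether labels were mixed. If 1 shift shared by the 8 WT SD libraries made the whole WT diet difference, that difference would be alike in both populations. However, 4363 genes differed in their WT diet effect between the populations. A shared shift behind part of the difference stays open, and these 8 libraries stood apart together on the third principal component. A batch of WT SD libraries acting differently on each population, which no label names, stays open for the WT counts. It would not explain the few KO calls, as no WT library is compared in the KO diet contrasts. A smaller diet response in KO mice also stays open and was not tested further.

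T cell transcripts were higher in KO than in WT libraries of both populations on HFD, though at low levels: Cd3e averaged 6.76 CPM in KO against 0.636 CPM in WT in CD11c+ cells and 11.4 against 1.52 CPM in CD206+ cells, and the most abundant list members were Cd2 at 42.8 CPM in KO CD11c+ and Cd4 at 57.3 CPM in KO CD206+ cells. A rise of all non-macrophage RNA alike is argued against by endothelial and stromal lists, the highest of whose 4 medians on HFD was -0.543, but other lists were also called higher at the preset correlation, of which the neutrophil list in CD206+ cells alone held with an estimated one: natural killer (medians 2.95 and 1.74), neutrophil (2.36 and 2.43) and monocyte lists (2.02 and 1.05) in CD11c+ and CD206+ cells, the dendritic cell list (1.55) in CD11c+ cells, and the adipocyte (1.52) and mesothelial (1.43) lists in CD206+ cells, so a rise of several cell types stays open. Within groups, libraries with more of 1 of the 19 T cell transcripts had more of the others, with a median pairwise correlation of 0.605 against a 95th percentile of 0.079 over 1000 random lists of like expression, which is consistent with T cells or their RNA in the sorted fractions, although the gates on CD11c and CD206 would remove most T cells. None of the 19 genes is on another of the lists, but Cd4 and Cd2 are also made by some myeloid cells, and Cd2 stood at 176 CPM in CD11c+ WT SD cells where Cd3e was at 2.31 CPM, so these members need not share that source. The neutrophil list likewise held members near the floor, such as S100a9 at 1.035 CPM in KO against 0.154 CPM in WT CD206+ cells on HFD. Its most abundant member there, Mmp9, also stood at 394.8 CPM, without TMM scaling, in CD206+ WT SD cells. A difference in the T cells of KO fat itself stays open and was not tested.

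Lyz1, singled out after its values were seen, was higher in KO than in WT on HFD, by 3.15 ± 0.24 (SE) in CD11c+ and 2.02 ± 0.23 in CD206+ cells on the log2 scale, while its paralog Lyz2 was not called (adjusted p by edgeR 0.322 and 0.281). Reads moving from Lyz2 to Lyz1 would leave their sum unchanged: in CD11c+ cells the lowest KO sum was 1.255 times the highest WT sum, which argues against this as the whole cause, but in CD206+ cells the ratio was 0.779 and it remains open. Strain sequence carried along with targeted loci could alter neighbouring genes, and if Lyz2 is the Cre locus, which is assumed from its common use alone, 76 genes lie within 5 Mb of Tnfaip3 or Lyz2, called with odds ratios from 0.844 to 1.46 against other genes. The highest upper bound of the 4 intervals was 2.45, so an effect on neighbours cannot be told apart from none with so few genes. A change of Lyz1 transcription with genotype also stays open and was not tested.

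For contrasts of 2 groups, chance can be excluded where other divisions of the same libraries rarely gave as many genes. Of the 35 divisions of 4 against 4 libraries, 1, the real one, gave as many as KO against WT in CD11c+ cells on HFD (5116, highest other 66) and on SD (3607, highest other 1308), in CD206+ cells on HFD (2930, highest other 163) and on SD (3300, highest other 2), between the diets in WT CD11c+ (6234, highest other 844) and CD206+ cells (3728, highest other 11), and between the populations in WT on HFD (2746, highest other 175) and SD (8565, highest other 1503). Same-numbered WT libraries pair the populations, and the real division parts all 4 pairs; the other 7 that do so gave at most 1 gene on HFD and 0 on SD, while the highest counts, 175 and 1503, came from divisions parting 2 pairs. For the diets in CD11c+ KO cells 11 of 35 divisions gave at least 1 gene (highest other 24), so the real count did not stand out. In CD206+ KO cells the real count was 0 (highest other 1), which all 35 divisions reach by definition, so the divisions test nothing there. For the interactions 100 divisions, the real one included, permuted genotype within each arm. As many genes came from 1 for diet in CD11c+ cells (3877, highest other 3057) and 2 for diet in CD206+ cells (1595, highest other 1723). For population 2 gave as many on HFD (586, highest other 2469) and 4 on SD (884, highest other 3280). Mixing the labels of an arm also breaks up its genotype difference, which was large in each arm (2930 to 5116 genes). A mixed division thus differs from the real one in more than the interaction. These draws therefore cannot tell whether an interaction count arose by chance. For population these draws break the same-numbered pairs, and some called several times the real count, which points to a structure of the samples. In the highest of each of the 4 sets 1 arm of 8 libraries had all its labels kept or all exchanged (0 or 8 in place) while the other was mixed (2, 6, 4 and 2 in place), so the genotype difference of 1 arm entered as an interaction. A further 35 divisions keep both libraries of each number in 1 genotype. On SD only the real one gave as many (884, highest other 1). The numbers pair the populations there, while the highest of the 100 draws gave 6 of the 8 pairs different genotypes. On HFD the numbers pair the WT but not the KO libraries, and 1 of these 35 gave as many (586, highest other 0). Every other division of the 35 mixes the genotypes in both populations, which breaks up the genotype difference. These 35 thus cannot tell either whether the counts for population arose by chance.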

How the results depend on the processing

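Every alternative here was planned but the replicate block in list tests, with a preset or an estimated correlation, which was chosen after the pairing and the first results were seen. The counts for KO against WT, for the diets in WT, for the populations in WT and for both interactions with diet stayed within 1.5 times under every alternative, leaving out each library included. Of 1714 pairs of a named gene and a contrast 1417 were called, of which 0 reversed and 1149 kept direction and call under every setting. Many were named for large changes in this fit, so this is no independent test. In 268 pairs a call was lost under at least 1 setting and in 83 gained. The diet count in CD11c+ KO cells, 1 in the planned fit, was 51 by DESeq2, 0 with only the compared groups and 0 with the replicate block. Leaving out libraries moved it between 0 and 80, as given in Results. In CD206+ KO cells, 0 by edgeR, it was 18 by DESeq2, 1 with no filter and 0 with the replicate block, and 0 to 7 when leaving out libraries. The interaction of genotype with population on HFD, 586 genes, gave 1209 with the replicate block and 306 to 700 when leaving out libraries. On SD, 884 genes became 1612 with the replicate block, and with only the compared groups fitted 50.3% of the called genes were higher against 62.3%. The cause was not tested. List calls fell from 207 to 11 with an estimated correlation.

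In KO HFD the correlations of same-numbered CD11c+ and CD206+ libraries ran from -0.176 to 0.503, and 4 of 8 libraries correlated best with their own number, so these share only a number; across genotypes and diets no pair of groups had every correlation above 0.1. There the block gave 5207 and 3748 genes for KO against WT in CD11c+ cells on HFD and SD, and 3050 and 3390 in CD206+ cells, all within 1.5 times. In the paired sets the block gave 3914 and 9064 genes between the WT populations on HFD and SD, so calls of many single genes changed, while the 117, 145 and 62 named genes called between the WT populations on HFD and SD and in the interaction with population on SD all stayed called. In their list tests 16, 13 and 6 calls became 20, 14 and 10 with the block, and 6, 0 and 0 with an estimated correlation as well. Voom's quality weights were lowest for CD11c+ WT SD replicate 4 (0.284) and CD206+ KO SD replicate 4 (0.507). A stricter filter left 10785 to 11829 genes and no filter 18929. Each simulated draw changed 200 genes. For KO against WT in CD11c+ cells on HFD 5116 were called in the data, so the Benjamini-Hochberg cut-off was stricter in simulation. For the diets in KO cells, with 1 and 0 calls, it was looser, so recovery in the data may be lower. Simulated shares thus do not give the recovery in the data.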

Other observations

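No test of these lists was chosen after the result was seen; the selection of lists to describe was. Cholesterol synthesis genes differed between the genotypes on SD. On SD they rose in KO in 8 of 22 cases in CD11c+ cells (10 adjusted over the list alone; median 0.46, camera adjusted p = 0.00151, adjusted p = 0.709 with an estimated correlation). In CD206+ cells 11 rose (12 adjusted over the list alone; median 0.57, camera adjusted p = 5.23e-05, adjusted p = 0.503 with an estimated correlation). The squalene epoxidase Sqle stood there at 1.30 ± 0.30 and farnesyl diphosphate synthase (Fdps) at 1.26 ± 0.25. On HFD the list was not called between the genotypes (camera adjusted p = 0.583 in CD11c+ and 0.277 in CD206+ cells). Its interaction with diet was negative in CD206+ cells (7 genes lower, 11 adjusted over the list alone; median -0.66, camera adjusted p = 1.02e-05, adjusted p = 0.554 with an estimated correlation). Cholesterol efflux genes rose on HFD in WT CD11c+ cells in 8 of 16 cases (8 adjusted over the list alone; median 1.03, camera adjusted p = 0.000256, adjusted p = 0.3 with an estimated correlation). The interaction with diet was negative for 8 (8 adjusted over the list alone; median -0.87, camera adjusted p = 0.000673, adjusted p = 0.394 with an estimated correlation).

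Genes of the inflammasome and of necroptosis rose in KO in 10 of 20 cases in CD206+ cells on SD (12 adjusted over the list alone; median 0.44, camera adjusted p = 2.18e-05, adjusted p = 0.0887 with an estimated correlation). On HFD 12 rose and 1 fell (12 and 2 adjusted over the list alone; median 0.30, camera adjusted p = 0.000352, adjusted p = 0.118 with an estimated correlation). On SD and HFD the necroptosis effector Mlkl stood at 0.99 ± 0.17 and 1.46 ± 0.17 and the protease Casp1 at 0.94 ± 0.10 and 0.93 ± 0.10. In CD11c+ cells on HFD 11 rose and 3 fell (12 and 4 adjusted over the list alone; median 0.49, camera adjusted p = 0.00724, adjusted p = 0.198 with an estimated correlation). Gsdmd, which forms pores during pyroptosis, rose by 1.17 ± 0.10. Hypoxia targets (camera adjusted p = 0.731 and 0.889) and genes of the unfolded protein response (camera adjusted p = 0.0701 and 0.179) were not called between the genotypes on HFD in CD11c+ and CD206+ cells.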
